A study of Triticum dicoccoides with 12 samples.

How the data were processed

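Total RNA from roots of wild emmer wheat (Triticum turgidum subsp. dicoccoides) was hybridised to the Affymetrix wheat genome array, a single-colour array on which each probe set is a group of short probes designed from bread wheat transcripts. The genotypes Y12-3 and A24-39 were compared at 4 weeks of age, either well-watered or after 7 days without water, per the labels. Each of the 4 groups had 3 arrays, labelled as biological replicates, which makes 12 arrays. The labels do not say whether an array held 1 plant or a pool.

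The deposited values are a score with 1 number per probe set and array, and RMA is the only tool named, per the submitters' processing notes, with no version. RMA is a background correction, normalization and summary method that usually gives log2 values on a shared distribution. The deposited score did not have that form. Its array means lay near 0, its SDs lay between 0.814 and 0.844, and the 12 distributions were not identical. The medians of the 3 arrays were -0.314, -0.300 and -0.301 in well-watered Y12-3, -0.304, -0.317 and -0.313 in stressed Y12-3, -0.332, -0.320 and -0.291 in well-watered A24-39, and -0.300, -0.316 and -0.310 in stressed A24-39. The base of the logarithm, the centring and any scaling are not given in the sources used here.

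The scale was examined with spike-in controls of known relative amount. With background taken from 23 control probe sets with no wheat target, the slope of signal on nominal amount should be 1 for the right base if the response is proportional. The hybridisation controls gave a slope of 0.996 ± 0.057 (SD, 12 arrays) for a natural logarithm and 0.745 ± 0.039 for log2. The poly-A spike-ins gave 0.951 ± 0.072 and 0.814 ± 0.069. The base was not settled by this, so differences are given in deposited units, and a ratio is given only for a few genes, under both readings. The fixed design had assumed log2 values. The values were used as deposited, without a further transformation.

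Each comparison was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 fit of 4 group means over all 12 arrays, with 8 residual degrees of freedom. The 111 control probe sets were left out, and Benjamini-Hochberg adjustment covered the other 61179 of 61290 probe sets, with a threshold of adjusted p under 0.05. The contrasts were the response to water stress in each genotype, the difference of these responses (the interaction), and Y12-3 minus A24-39 under each watering regime. Errors of differences are the moderated SE of limma, and errors of group means are SDs over 3 arrays. The number of arrays limits the precision. On simulated data, with 50 probe sets changed at each of 4 sizes, the stress test in Y12-3 recovered 48% of changes of 0.25, 76% of changes of 0.5 and 98% of changes of 1. The interaction test recovered 16%, 64% and 88% at the same sizes. The simulation changed few probe sets and used independent normal noise. The Benjamini-Hochberg threshold is less strict where many probe sets change, and real arrays can deviate together. These shares therefore describe the simulated setting and not the power of the real contrasts.

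The array annotation used here gave 1 gene symbol to 1273 of the tested probe sets (771 distinct symbols), several to 0 and none to 59906. All but 19 of these probe sets have placeholder symbols that begin with LOC and carry no description, and 0 of their gene identifiers were found in the RefSeq table of the assembly WEW_v2.1. Their functions are therefore not stated. The genes named were chosen by a rule fixed before the data were examined. For each contrast it took the 10 highest and 10 lowest differences among probe sets past the threshold that had exactly 1 symbol and no overlap between the 3 arrays of each group, with 1 probe set per gene and without the overlap condition for the interaction. At most the 2 highest and 2 lowest identifiers without a symbol were added per contrast. Members of the fixed lists were added by symbol, up to 4 per list and stress contrast, or the member with the smallest p where none passed. Among 3 against 3 arrays, 10% of probe sets separate completely by chance, against 33.7% for stress in Y12-3 and 27.1% in A24-39.

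The 22 gene lists fixed in advance were to be tested with camera and fry where 5 or more probe sets could be matched. No list reached 5, so 0 lists were tested, and the few matched members are given singly. The same-numbered arrays of the 2 genotypes were checked for pairing through the correlation of their deviations from the group means. These correlations were 0.197 to 0.278 in well-watered and 0.170 to 0.575 in stressed roots. Every one was over 0.1, the bound used for pairing. Arrays of different number correlated at -0.189 to -0.017 in well-watered and at -0.509 to 0.175 in stressed roots. The 0.175 was that of the first Y12-3 and the third A24-39 array, so the number marked no distinct pair for that Y12-3 array. With this limit, the numbers were treated as pairs between genotypes in the alternatives with a replicate block and in splits of paired differences. The main fit, with its errors and adjusted p values, used no pairing. In the comparisons between watering regimes the correlations of same-numbered arrays were -0.104 to 0.055 in Y12-3 and -0.039 to 0.126 in A24-39, and the numbers do not pair arrays there. Arrays of a group correlated at 0.968 to 0.991, and 0 pairs of arrays were identical.

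Alternatives set before the data were examined were the fit of only the 6 arrays compared, the replicate number as a block, an intensity trend with robust priors, array weights, a further quantile normalization, median centring, a filter on probe sets under the 40th percentile of the mean, a floor at the 20th percentile, a difference of at least 1, the removal of the 12726 probe sets with _s, _x or _a in their identifiers, and each array left out in turn. Alternatives chosen after seeing the data were the removal of the third array of both well-watered groups, a covariate for 3′ bias, a replicate block within each watering regime, a straight-line rescaling by the hybridisation and non-wheat tag controls, called rescaling by spike-in controls, and a fit of the 25 wheat control probe sets adjusted over these alone.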

Results

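Root transcript levels were measured on 12 wheat arrays, 3 for each combination of genotype (Y12-3 or A24-39, both wild emmer wheat) and watering (well-watered, or 7 days without water). In work on this species Y12-3 has been studied as a drought-resistant and A24-39 as a drought-susceptible genotype, and the design asks how their roots differ in the response to water stress. Between 33.0% and 47.8% of the probe sets lay above the brightest control without a wheat target on the same array. Where the lower of the groups compared had a mean at or under the highest mean of such a non-target control (-0.152), the difference is a lower bound and its rank is not exact. Between genotypes this bound holds for signal and not for expression, since a sequence difference under the probes could also put a group at background. Values are deposited log-like units of unstated base. If no scaling followed the logarithm, a difference of 1 unit is a ratio of 2.72 for a natural logarithm and of 2 for base 2. Whether any scaling followed is not known.

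In Y12-3 roots, the highest rise among genes with a symbol was that of LOC542888, from -0.55 ± 0.07 (SD, n = 3) in well-watered to 3.56 ± 0.22 (SD, n = 3) in stressed plants. Its difference was 4.11 ± 0.12 (SE, limma adjusted p = 1.07e-07), a lower bound since the well-watered mean was under the highest mean of a non-target control. If no scaling followed the logarithm, this is a ratio of at least 60.9 on the natural or 17.2 on the log2 reading. LOC542799, LOC542804, LOC543293 and LOC543084 rose by 4.06, 4.03, 3.91 and 3.89 units. LOC543476, LOC778392, LOC543108, LOC543255 and LOC100125736 rose by 3.49, 3.41, 3.07, 2.88 and 2.18. The largest fall was that of LOC543085, from 2.82 ± 0.26 to -0.30 ± 0.15 (SD, n = 3), a difference of -3.12 ± 0.14 (SE; limma adjusted p = 6.31e-07). LOC543422 (-3.03), LOC543313 (-2.74), LOC606308 (-2.60) and LOC543312 (-2.49) followed, and LOC778415, LOC543086, LOC606366, LOC543390 and LOC100037587 fell by 1.97 to 1.69 units. Not all probe sets of these genes changed: 2 of 3 rose for LOC778392 and 1 of 2 for LOC543108, and 2 of 3 fell for LOC778415 and 1 of 3 for LOC543422. The fall of LOC543422 had a wide error of 0.83 (limma adjusted p = 0.0271). For 7 of the 10 rising genes the well-watered mean was at or under the highest mean of a non-target control, and for 3 of the 10 falling genes (LOC543085, LOC543422 and LOC778415) the stressed mean was. The probe sets without a symbol that rose most were Ta.2638.1.S1_at (5.19) and Ta.14617.1.S1_at (4.90), both from well-watered means under that control. Those that fell most were Ta.9401.1.S1_a_at (-4.65) and Ta.5148.3.S1_x_at (-4.39).

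Over all probe sets, limma called 11716 changed by water stress in Y12-3, 6765 higher and 4951 lower, which is 19.2% of those tested. The median size of these changes was 0.36 units, and 1303 of them (560 higher, 743 lower) changed by at least 1 unit. Without the third stressed Y12-3 array the count was 7731. After rescaling by spike-in controls, chosen after seeing the data, it was 11701 with another split, 9161 higher and 2540 lower. The 3′ minus 5′ difference of the dap spike-in, a control transcript added before labelling, was 0.847 ± 0.041 in stressed and 1.25 ± 0.20 in well-watered Y12-3 (SD, n = 3 each; exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 allows). With that difference as a covariate, chosen after seeing the data, limma called 5647, 2787 higher and 2860 lower. The responses did not shrink in that fit (slope of 1.103 on those without the covariate), while the SE was 1.72 times as wide.

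In A24-39 roots, LOC542799, LOC543293 and LOC542888 rose most, by 4.82 ± 0.20, 4.62 ± 0.19 and 4.59 ± 0.12 units (SE; limma adjusted p = 4.92e-07, 4.92e-07 and 5.56e-08). For LOC542799 and LOC543293 the values given for the 2 genotypes come from different probe sets. For LOC543293, Ta.2704.1.S1_x_at rose by 4.62 in A24-39 and 3.73 in Y12-3, while TaAffx.46097.2.S1_at rose by 3.35 and 3.91. LOC542804, LOC543084, LOC543476, LOC543255 and LOC778392 rose by 4.04, 4.03, 3.68, 3.65 and 3.62, and LOC543108 and LOC542781 by 2.41 and 2.29. LOC543085 fell most, from 2.62 ± 0.11 to -0.34 ± 0.21 (SD, n = 3), followed by LOC543313 (-2.50), LOC543312 (-2.06) and LOC606366 (-1.98). LOC100037518, LOC543438, LOC543086, LOC542826, LOC543398 and LOC543397 fell by 1.84 to 1.65 units. Of the 10 rising genes 10 also passed in Y12-3 in that direction, and of the 10 falling genes 8 did. For LOC778392 2 of 3 and for LOC543108 1 of 2 probe sets rose here too. The well-watered means of LOC542888, LOC542804, LOC543084 and LOC543108 and the stressed means of LOC543085 and LOC606366 were under the highest non-target control, so these differences are lower bounds, as are those of the rising probe sets without a symbol. Among probe sets without a symbol, Ta.14617.1.S1_at (5.12) and Ta.9389.1.S1_at (4.95) rose most, and Ta.5148.1.S1_a_at (-4.65) and Ta.9401.1.S1_a_at (-4.44) fell most.

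limma called 6541 probe sets changed by water stress in A24-39, 3268 higher and 3273 lower, or 10.7% of those tested. At least 1 unit of change was seen in 1075 of them, 448 higher and 627 lower. Without the third stressed A24-39 array the count was 3866, and after rescaling by spike-in controls, chosen after seeing the data, it was 3272, 1324 higher and 1948 lower. The dap 3′ minus 5′ difference was 0.949 ± 0.061 in stressed and 1.15 ± 0.13 in well-watered A24-39 (SD, n = 3 each; exact permutation test, two-sided p = 0.1).

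**Figure D1:**
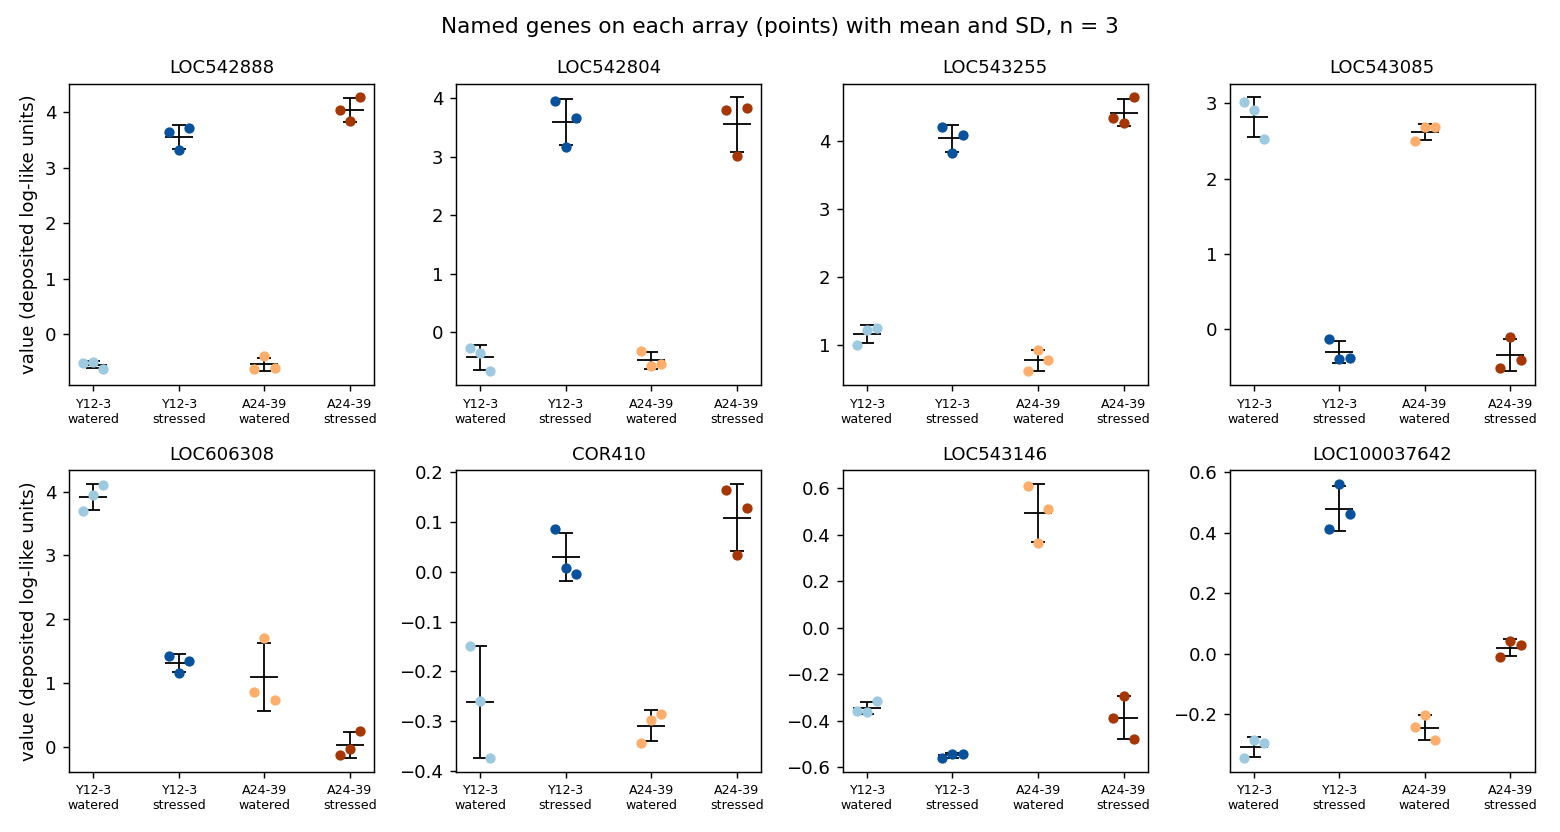
Deposited log-like values of 8 named genes on each of the 12 arrays (points), with the mean and SD of each group (n = 3). LOC542888, LOC542804 and LOC543255 were higher and LOC543085 lower in the stressed roots of both genotypes, and each panel has its own vertical scale.

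Few of the fixed lists could be followed by symbol. COR410, a cold-regulated dehydrin, was the single member matched in the list of dehydrins and related proteins. It rose by 0.29 ± 0.06 in Y12-3 and by 0.42 ± 0.06 in A24-39 (SE; limma adjusted p = 0.0044 and 0.0008), and it passed in both when adjusted over the list alone. Both rises are lower bounds, since both well-watered means (-0.26 and -0.31) were under the highest non-target control. TUBA, alpha-tubulin, had 2 probe sets. Ta.812.1.S1_x_at fell in Y12-3 by 0.44 ± 0.14 (SE; limma adjusted p = 0.0451), a call lost under several alternatives and with its sign turned (0.05) under the rescaling by spike-in controls. Ta.723.1.S1_at fell in A24-39 by 0.29 ± 0.03 (SE; limma adjusted p = 0.0003), to a mean under the highest non-target control. Adjusted over the list alone, 2 TUBA probe sets passed in Y12-3 and 1 in A24-39. XTH, a cell wall enzyme of the xyloglucan endotransglucosylase family, differed by -0.32 ± 0.17 in Y12-3 and by 0.32 ± 0.17 in A24-39 (SE), neither past the threshold. The 2 probe sets of CAT1, catalase, and the 4 of the shoot markers FBP and petC gave 0 calls in either genotype, over all probe sets and over the list alone. Those of CAT1 and petC, and 1 of the 2 of FBP, had all 4 group means under the highest non-target control, and the other FBP probe set had means of -0.22 to -0.11, so their lack of calls is no measure of a lack of response.

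The array also carries 25 control probe sets for wheat genes, which were tested apart and adjusted over these alone, a choice made after seeing the data. The 3′ probe set for sucrose synthase, an enzyme that splits sucrose, fell from 4.37 ± 0.18 to 2.91 ± 0.07 in Y12-3 and from 4.37 ± 0.25 to 3.28 ± 0.08 in A24-39 (SD, n = 3). The differences were -1.46 ± 0.12 and -1.09 ± 0.12 (SE; limma adjusted p = 3.7e-06 and 6.2e-05). The middle probe set fell by 1.24 ± 0.21 and 1.28 ± 0.21, and the 5′ probe set by 0.64 ± 0.22 and 0.69 ± 0.22 (SE; limma adjusted p = 0.071 and 0.056), not past the threshold. The 3′ minus 5′ difference of this transcript was 2.37 ± 0.05 in stressed and 3.19 ± 0.76 in well-watered Y12-3, and 3.25 ± 0.11 and 3.64 ± 0.24 in A24-39 (SD, n = 3 each; exact permutation test, two-sided p = 0.4 and 0.1). These tests do not settle whether the size of the fall depends on the position of the probes. The 18S ribosomal RNA probe set fell by 0.59 ± 0.16 and 0.64 ± 0.16 (SE; limma adjusted p = 0.022 and 0.018). In all, 1 control rose and 4 fell in Y12-3, and 0 rose and 3 fell in A24-39. The falls were those of the 3′ and middle sucrose synthase and the 18S probe sets, and in Y12-3 also that of a 3′ actin probe set. The actin probe set differed by -0.11 ± 0.03 (SE), and its mean over all arrays was under the highest non-target control. The rise in Y12-3 was that of the middle elongation factor 1-alpha probe set (0.35 ± 0.06, SE).

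The responses of the 2 genotypes were then set against each other, over arrays that they do not share. The main fit, however, gives both responses the same estimate of spread for each probe set, from all 12 arrays. Of the probe sets called in both, 2642 rose in both, where independent lists of these sizes would share 361.4, and 2565 fell in both, against 264.9. Opposite directions were found for 5, against 626.4. These baselines take all tested probe sets as equally likely to be called, which they were not. Of the 11716 calls in Y12-3, 10421 were called again among the 36707 probe sets kept by the filter on dim ones. Same-numbered arrays of the genotypes also deviated together, so the errors of the 2 responses may be correlated. The excess of shared rises and falls may therefore be overstated. The shared count of 5207 was 3870 in fits of only the 6 arrays compared, where each genotype has its own estimate of spread. It was 3358 without the third stressed A24-39 array and 2558 after rescaling by spike-in controls, chosen after seeing the data. Across all probe sets, which are not independent replicates, the differences correlated at Pearson r = 0.894 and Spearman rho = 0.665. Among the 6504 probe sets called in Y12-3 but not in A24-39, 92.0% had the same sign in A24-39, and 13 of them passed the interaction test.

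**Figure D2:**
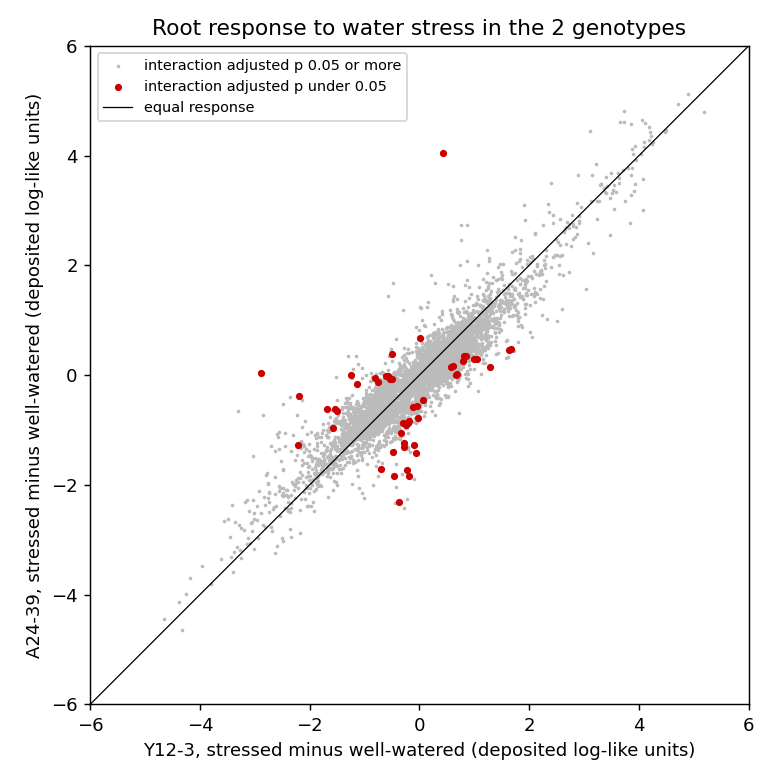
Response to water stress in Y12-3 (horizontal) against A24-39 (vertical), both as stressed minus well-watered in deposited log-like units, for probe sets that passed in any contrast with a difference over 0.5 or that have a gene symbol. The black line marks equal responses, the differences correlated at r = 0.894 over all probe sets, and red points are those past the interaction threshold, 52 over all probe sets.

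The interaction tests the difference of the 2 responses directly. limma called 52, of which 33 had a higher Y12-3 minus A24-39 response and 19 a lower one, and 2 had a symbol. LOC543146 fell from 0.49 ± 0.12 to -0.39 ± 0.09 in A24-39 and from -0.35 ± 0.03 to -0.55 ± 0.01 in Y12-3 (SD, n = 3), an interaction of 0.68 ± 0.09 (SE; limma adjusted p = 0.0253, and 0.0562 with the replicate number as a block). In both Y12-3 groups and in stressed A24-39 its mean was under the highest non-target control, so the size of the interaction is not exact. Its response in Y12-3 was not measured above background. On 1 of its 2 probe sets, LOC100037642 rose by 0.79 ± 0.04 in Y12-3 and by 0.26 ± 0.04 in A24-39 (SE), an interaction of 0.52 ± 0.06 (SE; limma adjusted p = 0.0101). Both well-watered means were under the highest non-target control, so this size is not exact. Its other probe set lay under that control in all groups and differed by 0.005 and 0.009. Without a symbol, Ta.6081.1.S1_a_at had the lowest interaction, -3.63 ± 0.26, with a rise of 4.05 ± 0.18 in A24-39 and a difference of 0.43 ± 0.18 in Y12-3 (SE). Ta.5252.1.S1_at followed with -2.92 ± 0.30, a difference of -2.89 ± 0.21 in Y12-3 and a difference of 0.03 ± 0.21 in A24-39 (SE). Both probe sets rose above the highest non-target control in 1 group only, stressed A24-39 for the former (3.69 ± 0.39) and well-watered Y12-3 for the latter (2.43 ± 0.56; SD, n = 3). Their differences in the other genotype were therefore not measured above background, and the sizes of their interactions are not exact. Ta.23066.2.S1_s_at (1.95 ± 0.21, SE) and Ta.18925.1.A1_at (1.64 ± 0.13, SE) fell in A24-39. The former rose above the highest non-target control in well-watered A24-39 only (1.69 ± 0.40, SD, n = 3), and the stressed Y12-3 mean of the latter (-0.25) was under it, so these interactions are not exact either. A fall of the former in Y12-3 could thus not be measured, and the well-watered Y12-3 mean of the latter (-0.05) lay near that control.

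The count of 52 and its direction rested on single arrays. Without the third well-watered Y12-3 array it was 625 (524 higher, 101 lower), without the third well-watered A24-39 array 141, and without both, a choice made after seeing the data, 1765. Without the second well-watered A24-39 array it was 64, the other refits gave 23 to 34, and array weights gave 865. Without the first well-watered Y12-3 array 13 were higher and 16 lower, and without the second 10 and 21. With a replicate block within each watering regime, added after seeing the data since same-numbered arrays of the genotypes were treated as pairs there, limma called 154, 90 higher and 64 lower. At an unadjusted p under 0.05, 5095 probe sets passed.

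In well-watered roots, LOC606308 was the gene most above A24-39 in Y12-3, at 3.918 ± 0.2001 against 1.098 ± 0.534 (SD, n = 3). The difference was 2.82 ± 0.22 (SE; limma adjusted p = 6.13e-05), and its second probe set differed by 2.66. LOC100037659 (0.99), LOC542869 (0.80), LOC778406 (0.60) and THI1.1 (0.60) were also higher in Y12-3. LOC606321, LOC100037594, LOC100037633, LOC780664 and LOC100037634 were higher by 0.41 to 0.30. Lower in Y12-3 were LOC543235 (-1.13), LOC543230 (-0.95), LOC543407 (-0.87) and LOC543146 (-0.84). LOC542821, LOC543148, LOC780610, LOC543184, LOC543441 and LOC543189 were lower by 0.69 to 0.61 units. Of the 10 higher genes 6 passed in stressed roots in that direction, and of the 10 lower genes 6 did. Without a symbol, Ta.5252.1.S1_at (3.01) and TaAffx.56982.3.S1_at (2.66) were highest and Ta.27457.5.S1_x_at (-3.56) and Ta.728.1.A1_at (-2.75) lowest. The lower groups of LOC778406, LOC606321, LOC543146, LOC542821, Ta.5252.1.S1_at and Ta.728.1.A1_at were under the highest non-target control, so their differences in signal are lower bounds. They are no bounds for expression, since the probe sequence may differ between the genotypes. Probe sets of 1 symbol could disagree: those of LOC100037659 ranged from -0.46 to 0.99 and those of LOC100037594 from -0.39 to 0.39, with calls in both directions, and calls were made for 1 of 2 probe sets of THI1.1, LOC100037634 and LOC543407, 1 of 4 of LOC780664 and 2 of 7 of LOC543184.

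limma called 3230 probe sets as different between well-watered genotypes, 1711 higher and 1519 lower in Y12-3, of which 309 differed by at least 1 unit. In the fit of the 6 arrays alone the count was 1473, without the first well-watered A24-39 array it was 1915, and after rescaling by spike-in controls, chosen after seeing the data, it was 1633.

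In stressed roots, LOC100049018 (1.40 ± 0.34), LOC606308 (1.29 ± 0.22) and LOC542869 (0.93 ± 0.14) were the genes most above A24-39 in Y12-3 (SE; limma adjusted p = 0.0294, 0.0053 and 0.0023). Of the 28 probe sets of LOC100049018, 2 passed. LOC542814 (0.82), LOC778406 (0.74), LOC100037659 (0.69), LOC542838 (0.63), LOC543463 (0.62), LOC780661 (0.59) and LOC542831 (0.56) were also higher, and for LOC543463 all 4 probe sets passed. Calls were made for 1 of 2 probe sets of LOC542814, LOC542799 and LOC100037526, 2 of 3 of LOC542838 and 1 of 6 of LOC780661, and in both directions for LOC100037659. Most below A24-39 were LOC543472 (-1.37 ± 0.18), LOC543235 (-1.32 ± 0.20), LOC780595 (-1.31 ± 0.35) and LOC542799 (-1.21 ± 0.20) (SE; limma adjusted p = 0.0011, 0.0023, 0.0437 and 0.0036). LOC543277, LOC543407, LOC543230, LOC100037526, LOC543018 and LOC543252 were lower by 0.99 to 0.86 units. LOC542799 was also among the genes that rose most under stress in both genotypes. Without a symbol, Ta.2434.3.A1_at (2.40) and TaAffx.105083.1.S1_at (2.37) were highest and Ta.6081.1.S1_a_at (-3.91) and Ta.14489.1.S1_at (-3.07) lowest. The differences in signal of these last and of LOC778406, LOC543277, LOC100037526 and LOC543018 are lower bounds, since the lower group was under the highest non-target control. For expression they are not, since the probe sequence may differ between the genotypes.

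limma called 5180 probe sets as different between stressed genotypes, 3103 higher and 2077 lower in Y12-3, of which 365 differed by at least 1 unit. Differences in both watering regimes and in 1 direction were found for 1082 higher and 977 lower probe sets, against 86.8 and 51.6 for independent lists, and opposite differences for 4. These baselines, too, take all tested probe sets as equally likely to be called, and both comparisons use the same estimate of spread for each probe set. Refits without 1 of the stressed arrays gave 2984 to 3402, except without the third A24-39 array, where the count stayed within 1.5 times. The hybridisation controls, added after labelling, averaged 2.34 ± 0.08 in stressed Y12-3 and 2.85 ± 0.12 in stressed A24-39 (SD, n = 3 each; exact permutation test, two-sided p = 0.1). After rescaling each array by these and the non-wheat tag controls, chosen after seeing the data, limma called 12907 probe sets, 93.0% of them higher in Y12-3, against 59.9% before.

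**Figure D3:**
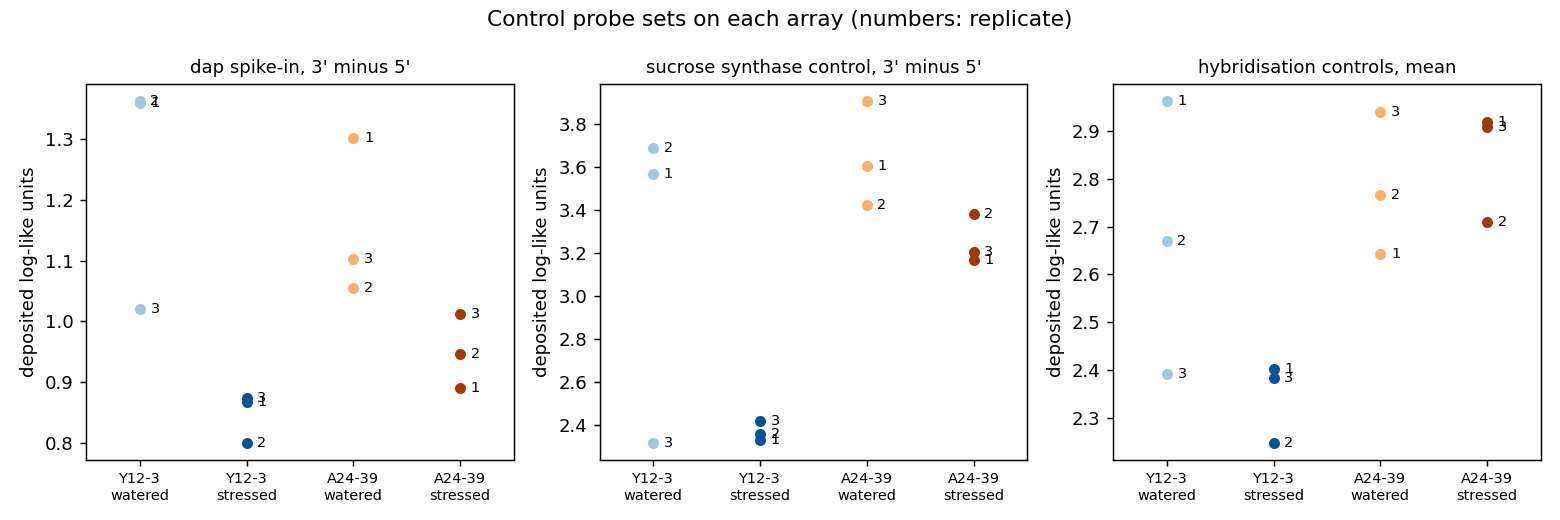
Control probe sets on each of the 12 arrays in deposited log-like units: the 3′ minus 5′ difference of the dap spike-in, that of the wheat sucrose synthase control, and the mean of the hybridisation controls, with the replicate number beside each point. The third well-watered Y12-3 array, with a dap difference of 1.02, lies below the other arrays of its group (1.36 on both), and stressed Y12-3 lies below stressed A24-39 in all 3 panels on average.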

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

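The tests of labelling, of array scale and of probe sequence were chosen after the results they bear on were seen, as were the removal of the third well-watered arrays, the rescaling, the covariate and the splits of paired differences. The test of labelling was first made on 1 array and that of probe sequence first on pairs of any size, and both were made stricter after those values were seen.

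The limma interaction test called 6 probe sets named by the fixed rule, each with 3 arrays in each of 4 groups. LOC543146 had an interaction of 0.68 ± 0.09 (SE; limma adjusted p = 0.0253), which no longer passed in 7 of the 12 refits without 1 array, with the replicate block or with the 3′ bias covariate. LOC100037642 had 0.52 ± 0.06 (SE), Ta.23066.2.S1_s_at 1.95 ± 0.21 and Ta.18925.1.A1_at 1.64 ± 0.13. Ta.6081.1.S1_a_at had -3.63 ± 0.26 and Ta.5252.1.S1_at -2.92 ± 0.30. LOC100037642 rests on 1 of its 2 probe sets. All 6 had at least 1 group mean under the highest non-target control, and LOC543146, Ta.23066.2.S1_s_at, Ta.6081.1.S1_a_at and Ta.5252.1.S1_at had 3 of 4, so the sizes are not exact. In LOC543146, Ta.23066.2.S1_s_at and Ta.5252.1.S1_at the genotype with the smaller response was under that control when well-watered, so a fall there could not be measured. Their well-watered differences (Y12-3 minus A24-39) were -0.84, -2.10 and 3.01. For Ta.18925.1.A1_at the well-watered Y12-3 mean (-0.05) was near that control and the difference -1.74. Sequence differences under the probes could give such values, so these calls alone do not show different responses. Of 100 assignments of the residuals of the additive fit, the real one included, 4 gave at least the 52 calls of the interaction, but moving single residuals breaks the pairs of same-numbered arrays. The highest other gave 1544 calls, many times the real count, and the reason for this was not tested. Splits of the 6 differences between paired arrays keep the pairs but are too few for a share under 0.05: as many calls as the real split were found in 1 of 10, the real one itself (154 calls, highest other 0). The other splits mix the watering regimes on each side, which widens the error where a difference is real, so their 0 calls are no measure of chance.

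Water stress changed 5207 probe sets in 1 direction in both genotypes while the 3′ minus 5′ differences of control transcripts also moved, so RNA quality or labelling could have shaped the responses. With the dap difference as a covariate, estimated within groups, the response did not shrink: the slope of the adjusted on the unadjusted response was 1.103 in Y12-3 and 1.05 in A24-39, and 1.03 or more in every refit without 1 array. Within groups the response thus did not follow the dap difference. That difference varied little within the stressed groups (SD 0.041 in Y12-3 and 0.061 in A24-39), which limits the test. The dap transcript was added before labelling and does not measure the quality of the root RNA. The 3′ minus 5′ difference of the wheat control G6PDH also moved with stress, by -0.55 in Y12-3 and -0.29 in A24-39 (exact permutation test, two-sided p = 0.1 each). The part of labelling or RNA quality in the shared response is therefore not settled. In the first version of the test, the third well-watered Y12-3 array, which shares the lower 3′ minus 5′ difference, deviated from the other arrays of its group along the A24-39 response with a slope of -0.011. The 10 splits of 6 arrays are too few for a share under 0.05. As many probe sets as the real split were found in 1 of 10 splits, the real one itself, in Y12-3 (10138 calls on these arrays, highest other split 0). In A24-39 it was again 1 of 10 (5016, highest other 0). Every other split mixes stressed and well-watered arrays on each side, so a real difference widens its error. The 0 calls there are thus no measure of calls made by chance.

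More probe sets were called in Y12-3 than in A24-39 (11716 against 6541). A lower scale of the stressed Y12-3 arrays cannot be told apart from the other explanations. The rescaling by spike-in controls gave a ratio of counts of 3.58, but by a lower count in A24-39 (3272) beside a similar one in Y12-3 (11701). Of the latter, 9117 were among the 11716 called before. The share of higher calls in Y12-3 moved from 57.7% to 78.3%, so a shift to 1 side takes part in that count. A larger response in Y12-3 is consistent with the median ratio of the sizes of the responses, 1.28 over 15012 probe sets chosen on the mean response and 1.23 without the third well-watered arrays, but it was as low as 1.15 without the third well-watered A24-39 array, and 1.096 for mean responses of at least 1 unit. Noise in Y12-3 would also raise that ratio. Differences in 3′ labelling cannot be told apart from it. With the covariate the ratio of counts was 1.03, but the covariate overlaps with watering and widened the SE 1.72 times in Y12-3 against 1.23 times in A24-39, so the lost calls are no evidence for labelling. The ratio of the sizes did not fall with the covariate (1.36, and 81.5% of probe sets larger in Y12-3 against 69.5%), though the wider error in Y12-3 also raises that ratio.

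Differences between genotypes on probes made from bread wheat could be differences of sequence rather than of expression. Over pairs of probe sets of 1 symbol from different clusters, the differences between genotypes correlated at -0.389 when well-watered (15 pairs of 8 symbols, 95% interval -0.726 to 0.385). Under stress they correlated at -0.169 (94 pairs of 27 symbols, -0.461 to 0.216). The stress responses correlated at 0.714 in Y12-3 and 0.763 in A24-39. These values met the first criterion for sequence differences. Stress responses were larger, however, so the test was remade on small differences. Over pairs under 1 unit the genotype differences correlated at -0.389 when well-watered and -0.003 under stress, and the stress responses at 0.254 in Y12-3 and 0.454 in A24-39. The correlation of genotype differences minus that of stress responses was -0.550 (95% interval -0.843 to -0.085). Against 0.5 of the stress correlation, the bound set for sequence differences, the interval reached from -0.655 to 0.082. Sequence and expression thus cannot be told apart for these probe sets, with few pairs and symbols that may cover several gene copies. As many calls as the real split were found in 1 of 10 splits, the real one itself, when well-watered (1473 calls on these arrays, highest other 0). Under stress it was again 1 of 10 (7474, highest other 0), where the 4 splits that part all 3 pairs included the real one and the other 3 gave 0. The other splits mix the genotypes on each side, so a real difference widens their error. Their 0 calls are thus no measure of calls made by chance.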

How the results depend on the processing

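Median centring, the floor and the filter on dim probe sets left all 5 counts and the overlap within 1.5 times, as did a further quantile normalization. A similar count does not mean the same calls: of the 52 interaction calls, 38 were called again after that normalization. The number of probe sets changed in 1 direction in both genotypes, 5207, was 878 with a difference of at least 1, 3285 without probe sets with _s, _x or _a, and 2558 after the rescaling by spike-in controls. With a difference of at least 1, which is a stricter threshold by construction, the counts were 1303 for stress in Y12-3, 1075 for stress in A24-39, 16 for the interaction, 309 between well-watered and 365 between stressed genotypes. Without probe sets with _s, _x or _a, which leaves fewer tested, stress in Y12-3 had 7730 and stress in A24-39 had 4176. Array weights gave 17674, 10843, 865 and 12280 for stress in Y12-3, in A24-39, the interaction and the stressed genotypes, with 75.4% of the interaction calls higher. The fit of the 6 arrays gave 1473 for well-watered genotypes, and the trend with robust priors gave 140 for the interaction. For these, the cause was not tested.

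The settings that follow were chosen after seeing the data. Without the third well-watered arrays, which had the lowest array weights (0.292 and 0.301), the interaction had 1765 and the stressed genotypes 9962. The 3′ bias covariate gave 5647 for stress in Y12-3. The rescaling gave 3272 for stress in A24-39, 100 for the interaction, 1633 for well-watered and 12907 for stressed genotypes. It moved the share of higher calls from 57.7% to 78.3% in Y12-3, from 63.5% to 87.0% in the interaction and from 59.9% to 93.0% between stressed genotypes. In A24-39 it moved that share the other way, from 49.96% to 40.46% (1324 higher, 1948 lower). Between stressed genotypes the median of all probe sets went from -0.024 to 0.070. For the interaction that share was 79.3% without the third well-watered arrays and 38.0% with the covariate. For these too, the cause was not tested.

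The replicate number as a block (pairing) gave 12160 for stress in Y12-3, 7325 for stress in A24-39, 43 for the interaction, 3377 for well-watered and 5287 for stressed genotypes, and 5888 for the overlap, all within 1.5 times. Of the 52 interaction calls without it, 30 were called again with that block. A replicate block within each watering regime, added later, gave 154 for the interaction, 3955 for well-watered and 5342 for stressed genotypes. Of the 52 interaction calls, 36 were called again with it.

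Leaving out 1 array at a time gave 7731 to 12957 for stress in Y12-3, 3866 to 7588 for stress in A24-39, 23 to 625 for the interaction, 1915 to 3585 for well-watered and 2984 to 7387 for stressed genotypes, and 3358 to 5490 for the overlap. Of the 112 values of named genes, 61 kept their side of the threshold under every alternative run, and their direction where they were past it. Of 2803 values under alternatives, 214 were no longer past the threshold in the same direction and 5 came to pass it. Among values past the threshold with or without the alternative, 1 changed sign: TUBA (Ta.812.1.S1_x_at) in Y12-3, from -0.442 to 0.050 after the rescaling. Sign changes of values that passed in neither fit were not counted. The alternatives for the gene lists were not run, since no list had 5 probe sets. Signal over background limits the dim probe sets, since at most 47.8% of the probe sets on an array exceeded its brightest non-target control.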

Other observations

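THI1.1, which no fixed list holds, fell under stress in Y12-3 by 0.98 ± 0.12 on Ta.23967.1.S1_s_at and by 0.71 ± 0.08 on Ta.23967.1.S1_x_at (SE; limma adjusted p = 0.0003 for both). In A24-39 the first also fell, with a difference of -0.42 ± 0.12, and the second differed by -0.07 ± 0.08 (SE; limma adjusted p = 0.0487 and 0.706). The interactions, -0.56 ± 0.17 and -0.65 ± 0.12 (SE; limma adjusted p = 0.381 and 0.112), did not pass, so a difference of response was not shown. XTH and the TUBA probe set Ta.812.1.S1_x_at were lower in stressed Y12-3 than in stressed A24-39, with differences of -0.70 ± 0.17 and -0.66 ± 0.14 (SE; limma adjusted p = 0.0278 and 0.0138). After the rescaling by spike-in controls, 93.0% of all calls between stressed genotypes were higher in Y12-3. The differences of XTH and TUBA may therefore depend on the array scale. The control probe set for the middle of elongation factor 1-alpha, chosen after its value was seen, was higher in stressed Y12-3 than in stressed A24-39 by 0.42 ± 0.06 (SE; limma adjusted p = 0.0004 over the 25 wheat controls alone). Its stressed A24-39 mean (-0.20) was under the highest non-target control, so this difference is a lower bound for the signal only. The 3′ and 5′ control probe sets of this gene went the other way, by -0.13 ± 0.05 and -0.02 ± 0.04 (SE; limma adjusted p = 0.076 and 0.736 over these controls), neither past the threshold. Their means over all arrays were also under that non-target control.

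Of the 52 interaction calls, 36 also differed between the genotypes when well-watered and 20 when stressed, and 6 had responses of opposite sign. A hypothesis set before its test was that well-watered Y12-3 roots may already lie closer to the stressed state than well-watered A24-39 roots. On the axis of the mean response over 15012 probe sets, the 3 well-watered Y12-3 arrays scored -0.537 ± 0.010 and the 3 of A24-39 -0.463 ± 0.040 (SD), a difference of -0.074 (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 allows). All 3 Y12-3 arrays scored lower on this axis, the opposite of what was predicted. However, the axis and its probe sets were taken from these same arrays. A larger response in Y12-3 or a constant difference between the genotypes could also move these scores. They therefore cannot decide which well-watered roots lay closer to the stressed state.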
